A study of Mus musculus with 135 samples.

How the data were processed

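RNA of single ovulated (metaphase II) mouse oocytes was measured by sequencing in wild-type (WT) animals and in animals lacking Tet1 or Tet2, of C57BL6/129 background, aged 2 to 4 months (young) or 10 to 12 months (old). RNA of purified primordial germ cells (PGCs) at E13.5 was measured in 1 WT library and 1 library labelled Tet2KO, each made from pooled embryos. Only the processed values were used here, and no reads were aligned.

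The authors deposited the oocyte data as gene counts, unnormalized, in 2 tables with 1 column per library. Per the file headers, both tables were made with featureCounts 1.6.2 and GENCODE mouse release 17 on fragments of mapping quality 30 or more, counting multi-mapped reads and reads that overlap several genes, without strand. The submitters' processing notes name HISAT2, SAMtools and the mm10 build, without versions. Because reads in an overlap count for each gene there, genes that overlap on the genome cannot be assigned a signal separately. The authors deposited the PGC data as FPKM, fragments scaled to gene length and library total, in 1 table that also holds the log2 ratio of the library labelled Tet2KO to WT, a false discovery rate and a call, all computed by the authors with a Poisson method. FPKM times gene length in kilobases summed to 1000110 in the WT and 999959 in the other PGC library, the smallest value is 0.01, and the depth of these libraries is unknown. The authors' deposited false discovery rates are quoted only as values of the authors' deposited table.

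The labels describe 135 samples, 133 of them oocytes. Of these, 94 oocyte libraries could be matched to a count column by name. The other 39 samples carry numbered titles and a label naming the table that has no column of that name. In 38 of them the title and the characteristics contradict each other, and none of the 39 was used. Apart from the table named, their titles repeat those of numbered libraries that were matched, so they may be the same libraries listed again. Another 39 count columns matched no label and were not used. The numbered libraries therefore came from one table and the remaining libraries from the other. The tables share the counter, the annotation and their 53715 genes, so they were joined, although the written plan had named 1 table for all sets. Of the gene identifiers, 95 had no symbol.

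Total gene counts per oocyte ranged from 2354503 to 12472307 with a median of 3985321, and all 94 libraries passed the minimum of 100000. Oocytes whose titles share an identifier were summed into 1 set, giving 13 sets, and the set was the replicate. The labels do not tie sets to animals, so all p-values measure the spread between sets. Numbered sets are written with the stem of their titles. Sets carry T-series or numbered names (S-series for the 1 set of old Tet2KO), and this naming coincides with the count table, except that the S-series set stands with the T-series. Between oocytes of a set, 342 pairs were compared, no pair was identical, and the chi-square per degree of freedom of their counts had a median of 18.5.

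Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, quasi-likelihood F test) on the summed counts of all 13 sets together. The model had 1 mean per group and a term for the naming series, which is estimated from young WT and young Tet1KO, the groups that hold sets of both series. Genes with a CPM (counts scaled to the library total) of at least 1 in at least 2 sets were tested, 14418 in all. The common biological coefficient of variation was 0.319, with 6 residual degrees of freedom. Old Tet2KO against old WT was fitted without the naming series (7 residual degrees of freedom), because group and series coincide there, and its lone set is assumed to vary like the others. The log2 changes of edgeR come from the fitted model at its default prior count. The log2 CPM used for gene lists and for limma have a prior count of 2. P-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. Means are given with the SD over sets and edgeR log2 changes with a standard error (SE). That SE is the absolute log2 change divided by the square root of the F statistic, so it depends on the prior count too. Where one group held 1 to 3 counts, the ratio of summed counts is given with its 95% counting interval. Against a group at 0 counts a lower bound is given, computed against 3 counts over the group. These intervals and bounds cover counting error only.

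Before the data were examined, the groups, the tests, the alternatives and 38 gene lists were written down, together with a rule for the genes named in the text. The rule names the Tet genes and every called gene where fewer than 10 pass (otherwise the 10 largest changes each way at a CPM of 10 or more). It also names up to 4 members of a called list that pass the threshold, by smallest p. In oocytes that last condition was not kept. The members named are those of smallest p that move in the direction of their list, whether or not they pass. They are examples of the list's direction and no separate evidence for it. For PGCs the rule names the 10 highest and 10 lowest ratios and up to 4 members of the lists on germ cells, meiosis, methylation and other cell types. Other genes named are said to have been chosen after their values were seen. In oocytes, 35 lists had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. In PGCs, with 1 library per group and no test, log2 ratios use FPKM with a pseudocount of 1 for the 6817 genes at 10 or more in the higher library. Each PGC list was set beside 10000 random lists of genes matched on mean expression (from the nearest 100 genes). Shares and counts of detected genes per group were compared by an exact permutation test, two-sided, of set medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used for these steps.

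The edgeR test was tested on simulated data made from these counts, with 50 genes changed at each size. In young Tet1KO against young WT it recovered 0% of 2-fold, 40% of 4-fold and 88% of 8-fold changes, and 4.39% of its calls were false. In old WT against young WT it recovered 6% of 4-fold and 58% of 8-fold changes. On the same data DESeq2 gave 17.3% false calls in the first comparison, and treating each oocyte as a replicate gave 86.3%. Recovery in old Tet1KO against old WT was 26% at 4-fold and 60% at 8-fold, with 6.86% false calls. In data simulated from the PGC table, a list lowered 2-fold was placed at percentile 0, and 2 of the 28 lists left unchanged also lay beyond the 5th or 95th percentile. That simulation varied each gene independently, while members of a real list can vary together between 2 libraries. The percentiles are therefore descriptive and give no error rate.

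The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, no naming series term, each oocyte as a replicate, limma with trend on set means, other depth minimums, a minimum of 2-fold, each set left out in turn, the T-series sets alone, and the table of numbered libraries alone. For PGCs a pseudocount of 0.1 and floors of 1 and 50 were tried. Scaling PGC counts by the library total could not be run because the PGC table holds no counts. After seeing the data, 4 alternatives were added: the count table as a term for old Tet2KO, and leaving out 1 leukocyte-rich oocyte of set S161, 1 oocyte of set Young_Tet1-/-_201, or 3 ribosomal-rich oocytes of set Young_WT__246. No comparison holds 3 or more sets in each group, so other splits of the sets were not counted.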

Results

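Transcripts of 94 single ovulated oocytes were counted across 6 groups. TET enzymes oxidise 5-methylcytosine in DNA. The labels give knockouts of Tet1 and of Tet2, and the comparisons ask which oocyte transcripts differ without either enzyme, in young and in old females. Young WT held 38 oocytes in 4 sets (T148, T211, T231 and Young_WT__246), young Tet1KO 15 oocytes in 2 sets (T146 and Young_Tet1-/-_201) and young Tet2KO 16 oocytes in 2 sets (T213 and T214). Old WT held 12 oocytes in 2 sets (Old_WT_365 and Old_WT_247), old Tet1KO 6 oocytes in 2 sets (Old_Tet1-/-_209 with 5 oocytes and Old_Tet1-/-_315 with 1), and old Tet2KO 7 oocytes in 1 set (S161). Total counts per oocyte lay between 2354503 and 9775977 in young WT, 3922286 and 12472307 in young Tet1KO, 3303999 and 6374555 in young Tet2KO. They lay between 2971657 and 10362312 in old WT, 3842975 and 8250490 in old Tet1KO, and 2510427 and 3633422 in old Tet2KO.

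The oocytes detected 16774 ± 573 genes in young WT (SD of set medians, n = 4 sets), 17865 ± 492.9 in young Tet1KO (n = 2) and 17485 ± 78.1 in young Tet2KO (n = 2). Detected genes numbered 16983 ± 232 in old WT (n = 2), 17238 ± 2.83 in old Tet1KO (n = 2) and 16869 in the old Tet2KO set. Counts of the protein-coding genes of the mitochondrial genome made up 1.18% ± 0.226 of the total in young WT, 0.725% ± 0.481 in young Tet1KO and 1.59% ± 0.216 in young Tet2KO. In old WT they made up 0.898% ± 0.0066, in old Tet1KO 0.575% ± 0.102 and in old Tet2KO 0.999%. No difference between these groups passed an exact permutation test of the set medians (share of these mitochondrial genes, young Tet1KO against young WT p = 0.267, young Tet2KO against young WT p = 0.267, old Tet1KO against old WT p = 0.333, old against young WT p = 0.133). The designs allow no p below 0.133 with 4 against 2 sets or 0.333 with 2 against 2.

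Tet1 transcripts were nearly absent from young Tet1KO oocytes: 2 counts in 15 oocytes against 495 in 38 young WT oocytes, 0.653% of the WT level (95% counting interval 0.0788% to 2.37%). The difference passed the edgeR test (adjusted p = 0.0136), from 3.11 ± 1.19 CPM in WT (SD, n = 4 sets) to 0.017 ± 0.024 (n = 2). Pnpla3 (chromosome 15, 84167837 to 84187236, mm10), which encodes a lipid droplet acyl hydrolase, rose from 1.92 ± 0.152 CPM in young WT to 68.1 ± 68.6 in young Tet1KO, a log2 change of 5.05 (SE 0.43, adjusted p = 0.0013). Gm49513, a gene model that overlaps it (84181914 to 84195881), rose with it, from 1.56 ± 0.315 to 34.2 ± 34.2 CPM (log2 change 4.43, SE 0.35, adjusted p = 0.0013). The counts do not tell the 2 genes apart. Among the other Tet genes, Tet3 was far more abundant than Tet1 in oocytes and stood at 604 ± 14.9 CPM in young Tet1KO against 662 ± 29.2 in young WT (adjusted p = 0.974). Tet2 stood at 1.68 ± 0.286 against 2.41 ± 0.705 CPM (adjusted p = 0.973).

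These 3 genes, 2 up and 1 down, were all that passed of 14418, while 691 had an unadjusted p under 0.05. DESeq2 called 30 genes on the same sums and limma on set means 0 (Pnpla3 log2 change 3.89, adjusted p = 0.351). The Pnpla3 rise was uneven within the group. All 8 oocytes of set T146 carried it at 71.4 to 145 CPM, but in set Young_Tet1-/-_201 only oocyte Young_Tet1-/-_201_8 did, at 128 CPM. The other 6 stood at 5.35 or less, within or just above the WT range that ends at 4.24. Without Young_Tet1-/-_201_8 the Pnpla3 call was lost (log2 change 4.46, adjusted p = 0.516) and 1 gene, Tet1, remained called. Tet1 itself kept its direction in every setting, but lost its call with limma on set means, in either naming series alone and without set T146, Young_Tet1-/-_201 or Young_WT__246 (adjusted p from 0.0618 to 0.326).

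As groups, 3 lists were lower in young Tet1KO at the preset correlation. Transcripts of cytosolic ribosomal proteins were lower in 74 of 83 members (median log2 change -0.55, adjusted p = 9.8e-14; adjusted p = 0.596 with an estimated correlation). Rplp0, of the ribosomal stalk, stood at 21.04 ± 1.67 CPM against 44.2 ± 11.03. Rps16, of the small subunit, stood at 12.5 ± 1.06 against 20.1 ± 7.64. The protein-coding genes of the mitochondrial genome were lower in 13 of 13 members (median -0.42, adjusted p = 7.4e-06; adjusted p = 0.596 with an estimated correlation). Among them mt-Nd1, a complex I subunit, stood at 1146 ± 446 against 1867 ± 288 CPM. Nuclear-encoded subunits of the respiratory chain were lower in 51 of 75 (median -0.27, adjusted p = 0.001; adjusted p = 0.739 with an estimated correlation). Ndufb5 of complex I stood at 5.02 ± 1.30 against 10.6 ± 4.00 CPM. Adjusted over the list alone, no member of these 3 lists passed. In the list of DNA methylation and demethylation genes, 1 of 23 did, Tet1. In 3 oocytes of set Young_WT__246 (Young_WT__246_10, Young_WT__246_11 and Young_WT__246_15) the ribosomal protein transcripts summed to 4034, 7698 and 4842 CPM, above the 2561 that no oocyte of another set exceeded. Without these 3 oocytes the ribosomal median was -0.01 (adjusted p = 0.974) and the respiratory chain median turned to 0.06 (adjusted p = 0.828), while the mitochondrial list stayed lower (median -0.36, adjusted p = 0.000305). Without set Young_WT__246 or without set Young_Tet1-/-_201 none of the 3 lists passed (adjusted p = 0.819 and 0.822, with mitochondrial, ribosomal and respiratory chain medians of -0.20, -0.07 and 0.06 in both).

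**Figure D1:**
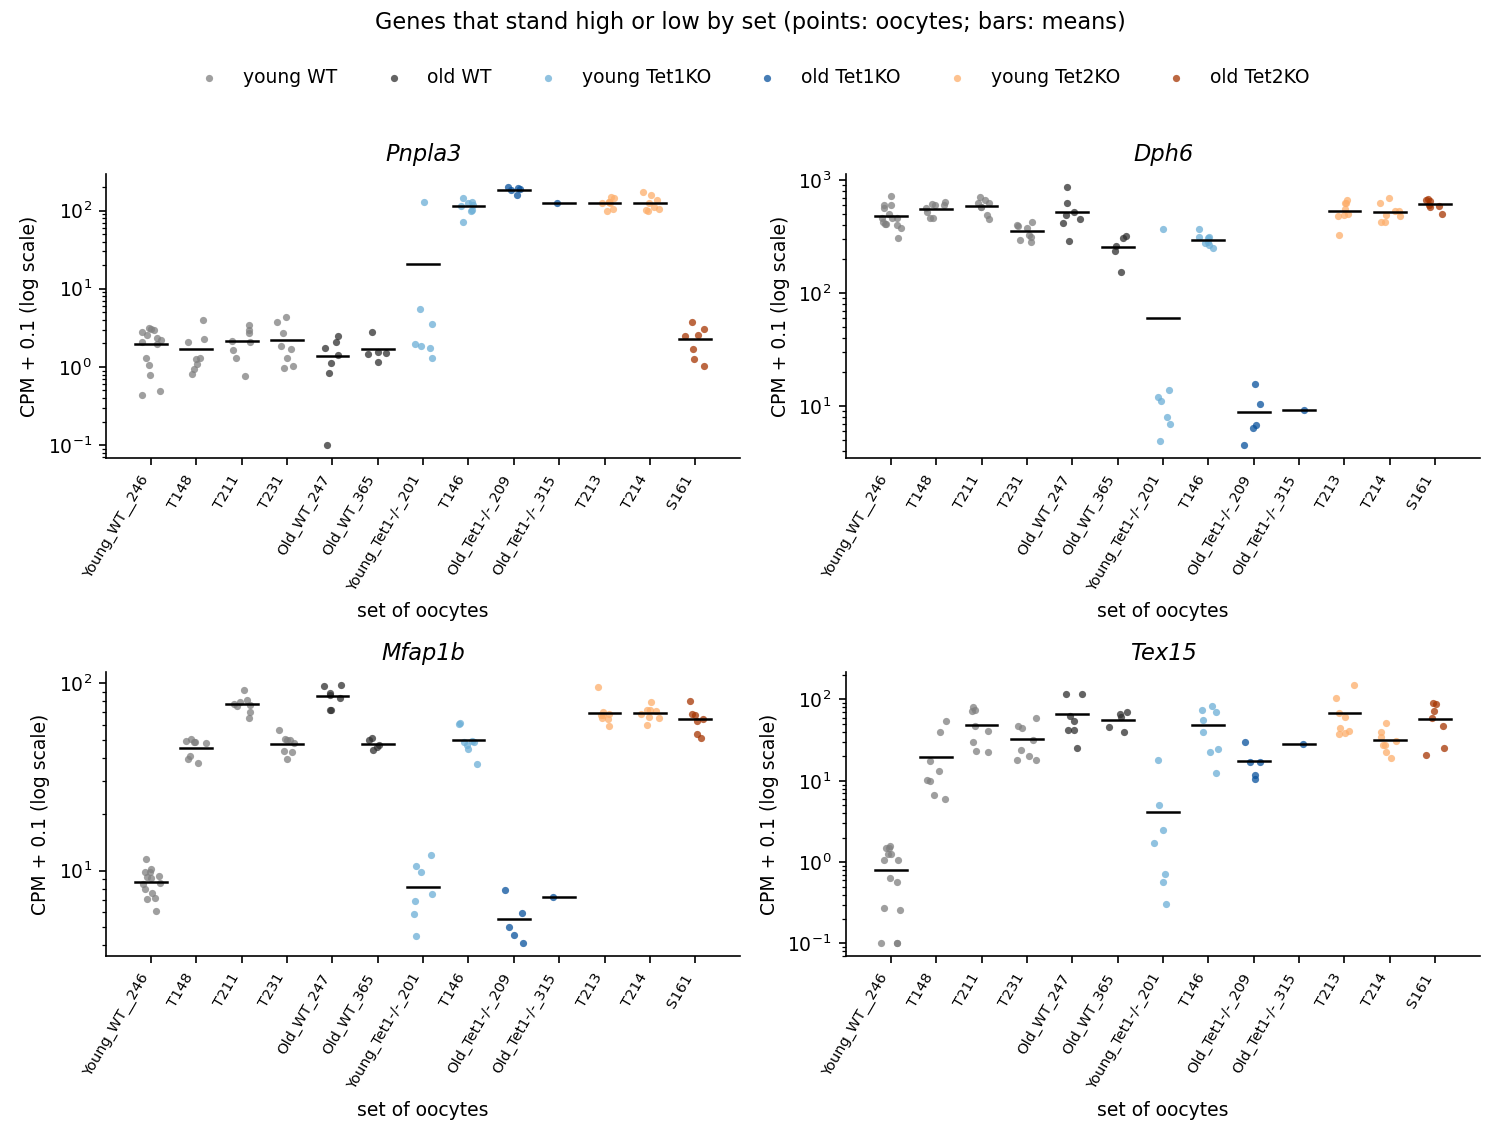
CPM of Pnpla3, Dph6, Mfap1b and Tex15 in each oocyte (points, log scale, 0.1 added), by set of oocytes on the horizontal axis and coloured by group, with a bar at each set's mean. Pnpla3 stands at 71.4 CPM or more in all oocytes of sets T146, T213, T214, Old_Tet1-/-_209 and Old_Tet1-/-_315 and in oocyte Young_Tet1-/-_201_8, and at 5.35 or less in the other oocytes.

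In young Tet2KO oocytes, Tet2 counts were lower but not absent: 84 in 16 oocytes against 327 in 38 young WT oocytes, 58.1% of the WT level (95% counting interval 45.2% to 74.1%). Tet2 stood at 1.24 ± 0.0836 CPM (SD, n = 2 sets) against 2.41 ± 0.705 (n = 4), a log2 change of -1.10 (SE 0.40) that did not pass the test (adjusted p = 0.822). Pnpla3 rose to 127 ± 2.09 CPM from 1.92 ± 0.152 in young WT (log2 change 5.68, SE 0.48, adjusted p = 0.0012). Gm49513, which overlaps it, rose to 69.5 ± 0.931 from 1.56 ± 0.315 (log2 change 5.07, SE 0.39, adjusted p = 0.000933). Every oocyte of both young Tet2KO sets carried Pnpla3 at 98.2 to 171 CPM. In the old Tet2KO set S161 it stood at 2.13 CPM, with 3.64 or less in each of 7 oocytes, within the WT range. Tet1 stood at 3.95 ± 0.131 against 3.11 ± 1.19 CPM (adjusted p = 0.922) and Tet3 at 674 ± 103 against 662 ± 29.2 (adjusted p = 0.999).

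These 2 genes were the calls of this comparison, with 835 genes at an unadjusted p under 0.05, 16 calls by DESeq2 and 0 by limma on set means (Pnpla3 log2 change 5.36, adjusted p = 0.0631). No gene list passed with camera at either correlation or with fry. Pnpla3 and Gm49513 were called in both young knockouts, which share their WT sets. With 20 simulations of unchanged groups against shared controls, the overlap had a median of 0 and a highest value of 0 (independent lists of these sizes would share 0.000277). When the WT sets were split between the knockouts both genes were still called in both. Pnpla3 stood at 1.71 to 2.05 CPM in all 4 young WT sets, so the split could hardly change this. The simulations drew each gene independently in each set and hold no genes that stand high or low by set. Both checks concern chance from the shared WT sets only, and not a difference between sets for another reason.

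Compared directly, young Tet1KO and young Tet2KO differed in 0 genes with edgeR (1345 at an unadjusted p under 0.05, 64 calls by DESeq2, 0 by limma on set means). Tet1 came closest, at 0.017 ± 0.024 CPM (n = 2 sets) against 3.95 ± 0.131 (n = 2, adjusted p = 0.0518). Tet2 stood at 1.68 ± 0.286 against 1.24 ± 0.0836 (adjusted p = 0.617) and Tet3 at 604 ± 14.9 against 674 ± 103 (adjusted p = 0.923). Mitochondrial-genome transcripts were lower in Tet1KO in 13 of 13 members (median -0.62, adjusted p = 2.9e-05; adjusted p = 0.959 with an estimated correlation). In it mt-Nd1 stood at 1146 ± 446 against 2471 ± 179 CPM and mt-Nd5, another complex I subunit, at 452 ± 191 against 1063 ± 162. Ribosomal protein transcripts were lower in 67 of 83 (median -0.44, adjusted p = 1.2e-07; adjusted p = 0.959 with an estimated correlation). In the ribosomal list 3 members were lower when adjusted over the list alone, Rpl17 standing at 26.9 ± 6.13 against 76.4 ± 27.9 CPM. Without set Young_Tet1-/-_201 neither list passed (mitochondrial median -0.42, adjusted p = 0.0669; ribosomal median -0.19, adjusted p = 0.302). Tet1 passed without oocyte Young_Tet1-/-_201_8 (adjusted p = 0.0497), the 1 gene called there.

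In old females, Tet1KO oocytes held 1 Tet1 count in 6 oocytes against 82 in 12 old WT oocytes, 2.31% of the WT level (95% counting interval 0.0578% to 13.2%; adjusted p = 0.137). Pnpla3 rose from 1.497 ± 0.105 CPM in old WT (SD, n = 2 sets) to 154 ± 43.4 in old Tet1KO (n = 2), a log2 change of 6.84 (SE 0.62, adjusted p = 0.0026). Gm49513 beside it rose to 77.8 ± 23.9 from 1.18 ± 0.0393 (log2 change 6.20, SE 0.51, adjusted p = 0.0019). Celsr1, a cadherin of planar cell polarity (chromosome 15, 85898929 to 86033777), rose from 9.09 ± 0.855 to 52.1 ± 10.0 CPM (log2 change 2.68, SE 0.32, adjusted p = 0.0138). Dph6, an enzyme of diphthamide synthesis (chromosome 2, 114516416 to 114654964, overlapped by Gm13972), fell from 414 ± 229 to 8.97 ± 0.163 CPM, a log2 change of -5.36 (SE 0.62, adjusted p = 0.0138). Mfap1b, a copy of the splicing factor gene Mfap1 (chromosome 2, 121460235 to 121474067), fell from 67.6 ± 28.9 to 6.23 ± 1.30 CPM (log2 change -3.28, SE 0.38, adjusted p = 0.0138). Tet2 stood at 1.62 ± 0.922 against 4.03 ± 1.03 CPM (adjusted p = 0.345) and Tet3 at 650.2 ± 95.4 against 748 ± 63.4 (adjusted p = 0.970).

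These 3 rises and 2 falls were all the calls, with 1794 genes at an unadjusted p under 0.05, 313 calls by DESeq2 and 5 by limma on set means, of which 4 were the same genes and Dph6 was lost (log2 change -5.13, adjusted p = 0.0636). Without the naming series term Mfap1b lost its call (-3.27, adjusted p = 0.623), and without Old_WT_365 Celsr1 did (2.80, adjusted p = 0.0989). Without old WT set Old_WT_247 no gene was called (1097 at an unadjusted p under 0.05), although the log2 changes stayed near the full fit (Pnpla3 6.76, SE 0.90, adjusted p = 0.0918; Dph6 -4.66, SE 0.59, adjusted p = 0.0918), and without old Tet1KO set Old_Tet1-/-_209 there were 16 calls, Dph6 (adjusted p = 0.0537) and Mfap1b (adjusted p = 0.0519) not among them. Without the 1 oocyte of set Old_Tet1-/-_315, Dph6 (log2 change -5.44, SE 0.90, adjusted p = 0.0892), Mfap1b (-3.57, SE 0.49, adjusted p = 0.0737) and Celsr1 (2.80, SE 0.35, adjusted p = 0.0737) lost their calls too, at log2 changes near the full fit. The low level of Dph6 was also found in 6 of the 7 young oocytes of set Young_Tet1-/-_201, at 13.7 CPM or less, where Young_Tet1-/-_201_8 stood at 365.3. Mfap1b stood at 8.51 CPM in young WT set Young_WT__246. Germline genes whose promoters are silenced by DNA methylation in somatic cells were lower in 19 of 23 members in old Tet1KO (median -0.34, adjusted p = 0.02, fry adjusted p = 0.0328; adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone, 3 members passed. Dazl, an RNA-binding protein of germ cells, stood at 779.8 ± 389 against 2089.7 ± 91.3 CPM, Sycp3, of the synaptonemal complex, at 27.9 ± 3.70 against 77.9 ± 19.4, and Hormad1, of the meiotic chromosome axis, at 0.166 ± 0.234 against 1.80 ± 1.004. Mitochondrial-genome transcripts were lower in 13 of 13 members (median -0.58, adjusted p = 0.0032; adjusted p = 0.719 with an estimated correlation). In it mt-Co1, of complex IV, stood at 1626 ± 299 against 2788 ± 542 CPM. Each list lost its call without 1 set, the germline list without set Old_WT_365 (median -0.41, adjusted p = 0.365) or Old_Tet1-/-_209 (median -0.33, adjusted p = 0.665) and the mitochondrial list without set Old_Tet1-/-_315 (median -0.32, adjusted p = 0.137).

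With age in WT oocytes, Tex15 and Spint1 rose and ribosomal protein gene Rps26 fell, after adjustment for the naming series. Tex15, which acts in meiotic recombination and piRNA-guided silencing (chromosome 8, 33516738 to 33585582), stood at 66.8 ± 12.4 CPM in old WT (SD, n = 2 sets) against 26.02 ± 20.3 in young WT (n = 4; log2 change 5.92, SE 0.72, adjusted p = 0.0224). Spint1, an inhibitor of serine proteases (chromosome 2, 119237362 to 119249527), stood at 5.88 ± 3.13 against 2.75 ± 2.38 (log2 change 5.86, SE 0.78, adjusted p = 0.0408). Mfap1b rose to 67.6 ± 28.9 from 44.4 ± 28.04 (log2 change 2.92, SE 0.40, adjusted p = 0.0408). Rps26 (chromosome 10, 128624534 to 128626747) fell to 18.5 ± 0.336 from 33.4 ± 32.8 CPM (log2 change -2.16, SE 0.26, adjusted p = 0.0224). The tau-tubulin kinase Ttbk1 (chromosome 17, 46442448 to 46487675) fell to 1.30 ± 0.211 from 6.64 ± 11.01 (log2 change -4.29, SE 0.52, adjusted p = 0.0224), with Gm47119, which overlaps it (log2 change -4.56, SE 0.49, adjusted p = 0.0224). Tet1 stood at 1.40 ± 0.346 against 3.11 ± 1.19 CPM (adjusted p = 0.443), Tet2 at 4.03 ± 1.03 against 2.41 ± 0.705 (adjusted p = 0.327) and Tet3 at 748 ± 63.4 against 662 ± 29.2 (adjusted p = 0.878).

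These 3 rises and 3 falls, with 1873 genes at an unadjusted p under 0.05, 331 calls by DESeq2 and 10 by limma on set means, were all the calls. Limma kept 5 of these genes and lost Spint1. In set Young_WT__246, the 1 young WT set of the numbered series, Tex15 stood at 0.645 CPM, Mfap1b at 8.51, Spint1 at 6 counts, Ttbk1 at 23.1 CPM against 1.46 or less in the other young WT sets, and Rps26 at 82.6 against 18.9 or less. Without set Young_WT__246 the log2 changes stayed about as large (Gm47119 -4.51, Ttbk1 -4.50, Rps26 -2.04, Tex15 4.71, Spint1 5.44, Mfap1b 2.91). Their SE rose to between 0.43 and 1.18, none of the 6 was called (adjusted p from 0.317 to 0.333) and 1 other gene was. In that fit the naming series term rested on sets Young_Tet1-/-_201 and T146 alone. Young_Tet1-/-_201 stood on the same side as Young_WT__246 (Tex15 3.30, Spint1 0.112, Mfap1b 7.79, Ttbk1 17.2 and Rps26 70.4 CPM). The sizes therefore carry over through that term and are no separate evidence of an age effect. Leaving out the 3 ribosomal-rich oocytes of set Young_WT__246 ended the call of Rps26 (log2 change -1.43, SE 0.32, adjusted p = 0.167) and kept the other 5. Without set Old_WT_365 or without set Old_WT_247 no gene was called (1711 and 1285 at an unadjusted p under 0.05), although the log2 changes stayed about as large (without Old_WT_365 Tex15 6.08, Spint1 6.30, Mfap1b 3.29, Rps26 -2.20, Ttbk1 -4.16 and Gm47119 -4.55; without Old_WT_247 5.71, 5.17, 2.40, -2.15, -4.47 and -4.60), and without the naming series term none was (437 at an unadjusted p under 0.05). The sizes rest on that term: without it the log2 changes were 1.35 for Tex15, 1.10 for Spint1, 0.59 for Mfap1b, -0.90 for Rps26, -2.42 for Ttbk1 and -2.75 for Gm47119, with an SE of 0.72 to 1.67.

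Gene groups of meiosis and chromosome segregation were higher with age in WT at the preset correlation. Spindle and checkpoint genes were higher in 30 of 38 members (median 0.30, adjusted p = 0.0093, fry adjusted p = 0.0238; adjusted p = 0.323 with an estimated correlation). Among them the checkpoint kinase Ttk stood at 67.4 ± 2.59 CPM in old against 59.7 ± 16.2 in young WT and the spindle motor Kif11 at 101 ± 0.0043 against 78.3 ± 18.2. Cohesin genes and their protectors were higher in 16 of 17 (median 0.29, adjusted p = 0.0195; adjusted p = 0.532 with an estimated correlation). The cohesin subunit Stag2 stood at 55.7 ± 1.36 against 32.4 ± 8.80. Meiotic prophase genes were higher in 30 of 37 (median 0.39, adjusted p = 0.0062; adjusted p = 0.323 with an estimated correlation), with 1 member, Tex15, up adjusted over the list alone. Terb1, which tethers telomeres in meiosis, stood at 77.3 ± 2.47 against 63.4 ± 9.69 CPM. DNA repair genes were higher in 40 of 51 (median 0.23, adjusted p = 0.0115; adjusted p = 0.532 with an estimated correlation), 1 up and 1 down adjusted over the list alone. The piRNA pathway was higher in 12 of 19 (median 0.37, adjusted p = 0.0454, fry adjusted p = 0.0238; adjusted p = 0.323 with an estimated correlation), 2 up and 1 down adjusted over the list alone. The tudor protein Rnf17 stood at 118 ± 8.71 against 101 ± 27.3.

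Ribosomal protein transcripts were lower with age in 74 of 83 members (median -0.87, adjusted p = 1.8e-12; adjusted p = 0.458 with an estimated correlation), 21 of them adjusted over the list alone. Respiratory chain subunits encoded in the nucleus were lower in 54 of 75 (median -0.35, adjusted p = 0.0093; adjusted p = 0.914 with an estimated correlation), 6 adjusted over the list alone. Cox6a1, of complex IV, stood at 114 ± 31.1 against 149.6 ± 108 CPM. Without the 3 ribosomal-rich oocytes of set Young_WT__246 both medians turned, to 0.08 (adjusted p = 0.774) and 0.25 (adjusted p = 0.0621). Of the higher lists only meiotic prophase still passed (spindle list adjusted p = 0.0621). Without set Young_WT__246 none of the 7 lists passed (adjusted p from 0.0688 to 0.783). In that fit the naming series term rested on sets Young_Tet1-/-_201 and T146 alone. The medians of the higher lists stayed positive (meiotic prophase 0.46, cohesin 0.47, spindle 0.24, DNA repair 0.20, piRNA 0.24), while the ribosomal median was -0.08 and the respiratory chain median turned to 0.31. None passed without the naming series term.

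**Figure D2:**
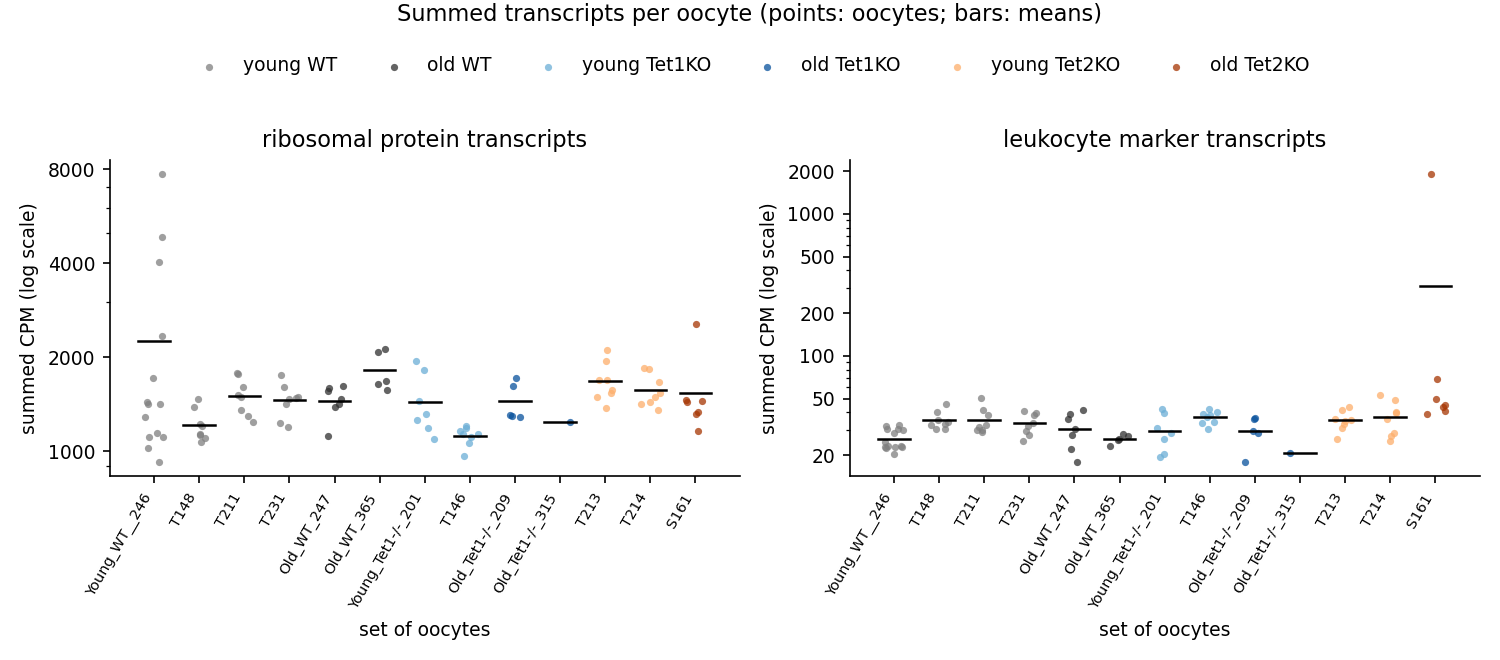
Summed CPM of the ribosomal protein list (left) and the leukocyte marker list (right) in each oocyte (points, log scale), by set of oocytes and coloured by group, with a bar at each set's mean. Oocytes Young_WT__246_10, Young_WT__246_11 and Young_WT__246_15 hold 4034, 7698 and 4842 CPM of ribosomal protein transcripts, and oocyte S1616 holds 1897 CPM of leukocyte transcripts.

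With age in Tet1KO oocytes, 2 genes fell, Ttbk1 from 8.94 ± 11.7 CPM in young (SD, n = 2 sets) to 0.537 ± 0.245 in old Tet1KO (n = 2; log2 change -4.76, SE 0.56, adjusted p = 0.0311). Gm47119 within it fell from 6.91 ± 9.07 to 0.179 ± 0.0818 (log2 change -6.02, SE 0.58, adjusted p = 0.0094). In young Tet1KO, Ttbk1 stood at 17.2 CPM in set Young_Tet1-/-_201 and 0.679 in T146. Tet2 stood at 1.62 ± 0.922 in old against 1.68 ± 0.286 in young (adjusted p = 0.796) and Tet3 at 650.2 ± 95.4 against 604 ± 14.9 (adjusted p = 0.792), and Tet1 was at or under 2 counts in both groups. Ribosomal protein transcripts were lower in 67 of 83 members (median -0.61, adjusted p = 0.0046; adjusted p = 0.955 with an estimated correlation). Its member Rpl32 stood at 28.9 ± 8.09 against 43.9 ± 20.2 CPM. The unadjusted p was under 0.05 for 1472 genes, and DESeq2 called 124 and limma on set means 3. Without set Old_Tet1-/-_209, which leaves 1 old oocyte, 181 genes were called, Ttbk1 and Gm47119 among them. Without set Old_Tet1-/-_315 only 1 other gene was called (Gm47119 -5.83, adjusted p = 0.113; Ttbk1 -4.53, adjusted p = 0.402). Without set Young_Tet1-/-_201 there were 11 calls, Ttbk1 not among them (-4.54, adjusted p = 0.105), and without T146 4 with both. The ribosomal list lost its call without T146 (median -0.22, adjusted p = 0.690) or Old_Tet1-/-_209 (median -0.86, adjusted p = 0.237).

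The effect of Tet1 loss itself did not differ between ages for any gene with edgeR (841 at an unadjusted p under 0.05, 17 calls by DESeq2, 0 by limma on set means). The ribosomal protein list was the 1 list to differ, with a median of 0.34, higher in 53 of 83 members (adjusted p = 0.0045; adjusted p = 0.78 with an estimated correlation). Its member Rps26 stood at 41.3 ± 13.3 CPM in old Tet1KO (SD, n = 2 sets) against 18.5 ± 0.336 in old WT (n = 2; interaction log2 1.40, SE 0.32, adjusted p = 0.813). The interaction of Tet2 was -0.83 (SE 0.58, adjusted p = 0.840) and that of Tet3 0.07 (SE 0.27, adjusted p = 0.974). Without the 3 ribosomal-rich oocytes of set Young_WT__246 the list's median turned to -0.12 (adjusted p = 0.592), and without set T146 3 genes were called.

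In the 1 set of old Tet2KO oocytes, Fth1, the heavy chain of the iron store ferritin (chromosome 19, 9982703 to 9985092), stood at 203 CPM against 15.1 ± 4.57 in old WT (SD, n = 2 sets; log2 change 3.74, SE 0.34, adjusted p = 0.003). Ctsb, a lysosomal protease (chromosome 14, 63122462 to 63145923, overlapped by Fdft1), stood at 91.9 against 14.2 ± 4.18 CPM (log2 change 2.69, SE 0.32, adjusted p = 0.0265). Leukocyte markers were higher in 6 of 6 tested members (median 1.68, adjusted p = 5.2e-14; adjusted p = 0.0123 with an estimated correlation, fry adjusted p = 0.0024), 5 of them adjusted over the list alone. Lyz2, the lysozyme of myeloid cells, had 3094 counts against 0 in old WT, at least 2604-fold higher against 3 counts over the group (adjusted p = 0.196). C1qb, a complement protein of macrophages, stood at 32.9 against 2.16 ± 0.350 CPM (adjusted p = 0.951). With Lyz2 at its bound the list's median was again 1.68. Tet2 stood at 1.27 against 4.03 ± 1.03 CPM (log2 change -1.67, SE 0.62, adjusted p = 1), 28 counts against 237, 29.8% of the WT level (95% counting interval 19.4% to 44.2%). Tet1 stood at 3.68 against 1.40 ± 0.346 CPM (adjusted p = 1) and Tet3 at 652 against 748 ± 63.4 (adjusted p = 1).

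These 2 genes were the calls, with 267 at an unadjusted p under 0.05, 11 calls by DESeq2 and 0 by limma on set means (log2 change 0.85 for Fth1 and 0.94 for Ctsb, adjusted p = 1). Both rest on oocyte S1616, which also holds 16 of the 28 Tet2 counts (log2 change of Tet2 without it -2.65, SE 0.68, adjusted p = 1), with 1280.0 CPM of Fth1 and 525 of Ctsb where the other 6 had 39.6 and 23.7 or less, and with 1897 CPM of summed leukocyte markers against 68.3 or less. Without S1616, Fth1 (log2 change 0.20, adjusted p = 1) and Ctsb (log2 change 0.26, adjusted p = 1) lost their calls, no gene was called (227 at an unadjusted p under 0.05) and the list's median was 0.50 (adjusted p = 0.0002). Group, naming series and set coincide here, so the set and the genotype cannot be told apart. The lone set has no spread of its own, and each SE and p-value of this comparison, those of the list included, assumes that it varies like the other groups. With the count table as a term 1 gene, Fth1, was called, and without Old_WT_247 neither was (Fth1 3.43, adjusted p = 0.0696; Ctsb 2.38, adjusted p = 0.537).

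In PGCs at E13.5, an embryonic age at which germ cells of a fetal ovary enter meiosis, 1 WT library was compared with 1 library labelled Tet2KO, without replicates or a test. Tet2 stood close to WT in the library labelled Tet2KO, at 2.96 FPKM against 3.19 (log2 ratio -0.08), so its level does not show the knockout that the label names. Tet1 stood at 16.8 against 10.3 FPKM and Tet3 at 0.88 against 1.5. Of 19004 genes, 6817 reached 10 FPKM in the higher library, and of these 8 were at least 2-fold higher and 60 at least 2-fold lower in the library labelled Tet2KO. The authors' deposited table calls 56 genes Up and 571 Down, and gives Tet2 a log2 ratio of -0.11 and a false discovery rate of 0.382.

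Meiotic and germline genes were lower in the library labelled Tet2KO. Of the meiotic prophase genes 25 of 28 were lower (median log2 ratio -0.37, percentile 0 of 10000 matched random lists). Stra8, a trigger of meiotic entry, stood at 71.6 against 138 FPKM, Sycp1, of the synaptonemal complex, at 12.1 against 26.3, and Meioc, a regulator of meiotic entry, at 8.22 against 16.6. Of the germline genes silenced by promoter methylation in somatic cells 22 of 28 were lower (median -0.38, percentile 0). Taf7l, a germ cell transcription factor, stood at 3.70 against 19.2 FPKM, Tex101 at 12.4 against 40.9, and the ADP/ATP carrier Slc25a31 at 33.2 against 63.2. The piRNA list was lower in 11 of 13 (median -0.13, percentile 3.17). Pluripotency and early germ cell genes were higher in 33 of 35 (median 0.19, percentile 100). L1td1 stood at 60.5 against 36.9 FPKM, Klf2 at 81.8 against 51.8, Tfcp2l1 at 10.7 against 6.82 and the cadherin Cdh1 at 37.8 against 25.4. Percentiles of 0 and 100 are the limits of 10000 lists. Genes of male germ cells were lower in 7 of 9 (median -0.07, percentile 18.2) and the methylation list was near even (median -0.001, percentile 50.3), with the glycosyltransferase Ogt, a TET partner, at 37.03 against 28.9 FPKM.

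Transcripts of blood and of gonadal somatic cells were lower too. All 7 erythroid genes were at least 2-fold lower (median -1.64, percentile 0). The globins stood lower, Hbb-b1 at 41.3 against 306 FPKM, Hbb-b2 at 28.8 against 148.1, Hba-a2 at 124 against 498 and Hba-a1 at 382 against 1192. Markers of gonadal somatic and interstitial cells were lower in 5 of 6 (median -0.71, percentile 0.07), with Gata4 at 6.38 against 18.5 FPKM and Wt1 at 9.45 against 21.7. Nr5a1, a regulator of steroid synthesis, had a log2 ratio of -1.62. At a floor of 1 FPKM, pregranulosa markers were lower in 13 of 13 (median -0.98, percentile 0). Examples were Wnt6, Irx3, Rspo1 and Lhx9 at 5.93, 10.3, 4.94 and 7.26 FPKM against 20.7, 26.3, 11.4 and 15.5. At that floor cumulus and granulosa markers were lower in 8 of 12 (median -0.48, percentile 0.43), Sertoli markers in 5 of 7 (median -0.39, percentile 6.09), endothelial markers in 9 of 10 (median -0.36, percentile 4.95) and leukocyte markers in 8 of 8 (median -0.13, percentile 62).

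Imprinted genes were lower in 18 of 26 (median -0.35, percentile 0), but at a floor of 1 FPKM the list lay at percentile 6.66 (27 of 43 lower, median -0.12). Lower too were immediate early genes in 9 of 12 (median -0.38, percentile 0). Small shifts were found in respiratory chain subunits (lower in 57 of 77, median -0.12, percentile 0), ribosomal proteins (lower in 63 of 85, median -0.08, percentile 4.02). Others were cohesin (higher in 13 of 17, median 0.16, percentile 99.8), DNA repair (28 of 41, median 0.08, percentile 99.5), endoplasmic reticulum stress (16 of 22, median 0.11, percentile 99.7), heterochromatin silencing (13 of 23, median 0.10, percentile 98.3), polycomb (18 of 27, median 0.09, percentile 98.1) and spindle genes (28 of 37, median 0.07, percentile 95.95). In all, 9 of 29 lists lay under the 5th and 7 above the 95th percentile. Gene models and pseudogenes, 1 of them among the 8 at 2-fold or more, are left out of the single genes named. The highest ratios were those of Eif3j2 (22.5 against 1.43 FPKM) and Rpl34 (1147 against 140.0). The lowest included Mir7654 (listed at 0.01 against 33.2) and Kctd14 (10.7 against 39.2). Rpl34 was mirrored by its pseudogene Rpl34-ps1 (74.3 against 1174 FPKM, chosen after its values were seen). Next highest were Rpl30 (275 against 112) and Mir3960, Snord99, Mir3113, Snord32a, Zfp534, Morf4l1b and Dynlt1b, with log2 ratios from 0.96 to 2.52. Of these the authors' deposited table calls only Rpl30 and Zfp534 Up. Its false discovery rates for the small RNAs Mir3960, Snord99, Mir3113 and Snord32a are 0.0346, 0.378, 0.141 and 0.233. In the table, 27 rows had a symbol that reads as a date and 4 rows a symbol that occurs in more than 1 row.

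**Figure D3:**
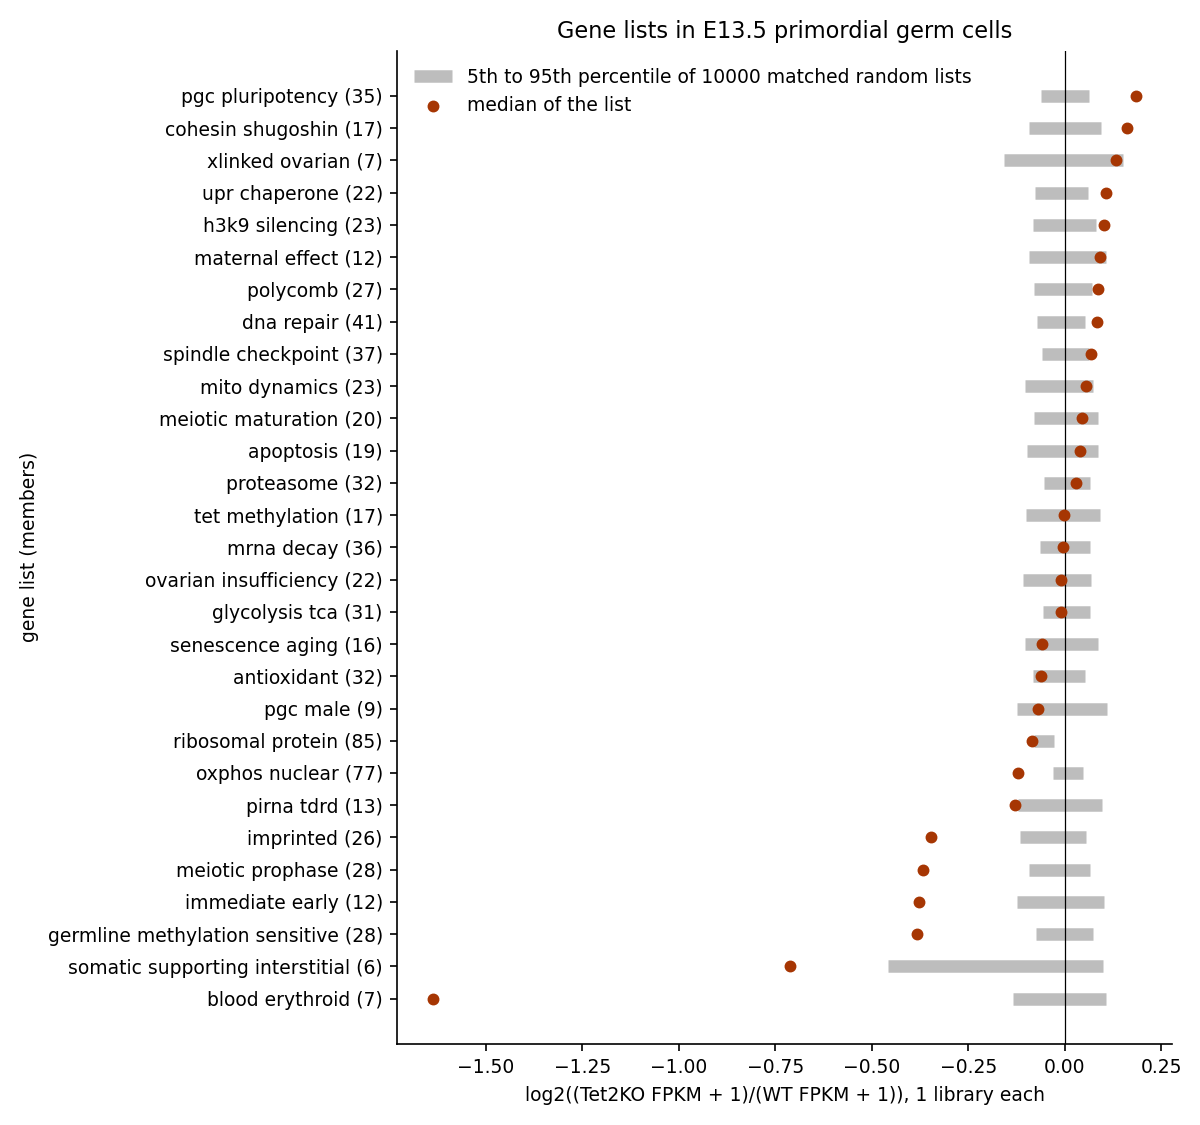
Median log2 ratio of FPKM (1 added), library labelled Tet2KO over WT, of each gene list with at least 5 members at 10 FPKM or more (points), beside the 5th to 95th percentile of 10000 matched random lists (bars), with the number of members in brackets. The erythroid list lies lowest at -1.64, the meiotic prophase list at -0.37 lies below its random range and the pluripotency list at 0.19 above it.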

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

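The test on RNA of cumulus or granulosa cells and the tests of gene lists between ages were written before their results were seen, and the other tests of this part were chosen after.

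Pnpla3, Dph6, Mfap1b and Tex15 stood high in some sets and low in others. Of 8340 genes at 10 CPM or more in a set, 55 split the 13 sets with a gap of 2 or more on the log2 scale. WT sets lay on both sides in 51 of them. The number that followed the knockout exactly was 0, but this required all 7 knockout sets of both genotypes on 1 side. A gene changed by loss of 1 enzyme alone could not meet it, so no conclusion is drawn from the 0. By set sums Pnpla3 was high in 6 of 7 knockout and 0 of 6 WT sets, and Dph6 low in 2 knockout and 0 WT sets. In set Young_Tet1-/-_201 these sums rest on oocyte Young_Tet1-/-_201_8 (set median 1.88 CPM for Pnpla3 and 11.1 for Dph6). Celsr1 stood at 23.8 to 59.2 CPM in the Tet1KO sets and at 13.1 or less in the WT and Tet2KO sets. For loss of a TET enzyme alone, in 5 of the 7 combinations of called gene and genotype a share of at least 0.25 of the knockout oocytes lay within the range of all 50 WT oocytes. Without Gm49513, which shares its signal with Pnpla3, this held in 3 of 5 (Mfap1b 15 and Dph6 9 of 21 in Tet1KO, Pnpla3 7 of 23 in Tet2KO). Oocytes of a set are not independent, so these shares argue against that explanation only for Mfap1b. Its oocytes within the range came from every Tet1KO set, and WT set Young_WT__246 stood low too (8.51 CPM). For Dph6, 8 of the 9 were from T146, whose 8 oocytes stood at 250 to 369 CPM. The 15 young Tet1KO oocytes held 2 Tet1 counts in all, so loss of Tet1 alone did not bring Dph6 low in T146. A part for it elsewhere stays open, since the old Tet1KO oocytes stood at 15.7 CPM or less against a WT minimum of 154. For Pnpla3, 5 of 21 in Tet1KO were from Young_Tet1-/-_201 and the 7 in Tet2KO all of old set S161. By these labels loss of 1 enzyme alone did not raise Pnpla3 in those oocytes, and a part for it elsewhere stays open. For Celsr1 (3 of 21) the explanation stays open. Variants linked to the targeted loci are argued against, since 0 of 5 called genes lay within 20 Mb of Tet1 or Tet2. Strain variants against the reference remain a candidate explanation in this C57BL6/129 background: the 188 genes at p under 0.001 formed 81 pairs lying 50 kb to 2 Mb apart, against a median of 41 and a highest value of 75 in 10000 random draws of tested genes (permutation p = 1e-04, the smallest these draws can give). With gene models left out, 151 genes formed 54 pairs against a median of 28 (highest 59, permutation p = 0.0007), and neighbours that share regulation for another reason remain open too.

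Summed over the set, ribosomal protein transcripts were higher in young WT set Young_WT__246 than in the other young WT sets, through the 3 oocytes Young_WT__246_10, Young_WT__246_11 and Young_WT__246_15 (the median oocyte of the set held 1417 CPM, against 1502 in T211, 1474 in T231 and 1173 in T148). RNA of cumulus or granulosa cells was not decided: over the 14 oocytes of the set the summed cumulus and granulosa list went down with the ribosomal sum (Spearman rho -0.65, permutation p = 0.014; Pearson r -0.71, permutation p = 0.0019; -0.45 and -0.53 without the 2 oocytes farthest from the median; the 1 relation computed), but Serpine2, which oocytes express, made up 93.8% to 95.2% of that sum in the 3 oocytes, so the relation does not measure those cells. The 17 of 27 list genes with a median of 0 in oocytes of other sets summed to 0.683, 0.409 and 1.34 CPM in them, against a median of 0.233 and a highest value of 1.08 in the other 11 and a highest value of 31.1 in other sets, which leaves it open. Gene length bias is argued against, since lists matched on coding length and expression had a median log2 difference of 0.0925 (highest 0.43) where the 82 ribosomal proteins with a coding length had 1.21. A difference in RNA capture within the set stays open and was not tested (mt-Rnr2, a mitochondrial ribosomal RNA, stood at 14594 to 23149 CPM in the 3 oocytes against a median of 2557 in the other 11), and no biological explanation was tested, since the labels name no difference within a set.

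In the PGC library labelled Tet2KO, meiotic genes were lower and pluripotency genes higher than in WT. A smaller share of germ cells is argued against, since the pluripotency list lay at percentile 100 of matched random lists. Fewer gonadal somatic and blood cells could account for the lower erythroid and somatic markers, but not for the whole pattern, since the meiotic list lay at percentile 0. Embryos at an earlier point of meiotic entry and loss of Tet2 cannot be told apart with 1 library per group.

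Over 71 groups of 4 to 10 sets or oocytes, 15 held a sample far from the others. Independent groups would give 3.55 by chance, but that number is no yardstick here. The genes tested were the Tet genes and those already called in these data, some of them through these same samples. Some of the measures also overlap. Set Young_WT__246 lay far above the other 3 young WT sets in Gm47119 (17.3 CPM, next 0.769), Ttbk1 (23.1 CPM, next 1.46), Rps26 (82.6 CPM, next 18.9) and the summed nuclear-encoded respiratory chain subunits (3804 CPM, next 2989). In old Tet1KO, oocyte Old_Tet1-/-_209_7 was the 1 oocyte of 6 with any Spint1 (0.463 CPM) and any Tet1 (0.232 CPM, 1 count). Oocyte Old_Tet1-/-_315_1 had a total count of 8250490 where the next had 4775724. Oocyte Old_Tet1-/-_209_6 had a share of 1.51% of counts on protein-coding mitochondrial genes (next 0.771%) and 15121 CPM of mitochondrial-genome transcripts (next 7707). In old Tet2KO, oocyte S1616 lay far above the other 6 in leukocyte markers (1897 CPM, next 68.3), Fth1 (1280.0 CPM, next 39.6), Ctsb (525 CPM, next 23.7), Tet2 (4.93 CPM, next 1.32), Rps26 (37.6 CPM, next 25.3) and ribosomal proteins (2561 CPM, next 1461.98). The effect of Tet1 loss on ribosomal protein transcripts differed between ages by a median of 0.34 on the log2 scale (53 of 83 members higher, adjusted p = 0.0045 with camera at the preset correlation and 0.78 with an estimated one), and by -0.12 without the 3 ribosomal-rich oocytes.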

How the results depend on the processing

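The settings that use the count table as a term, or leave out oocyte S1616, oocyte Young_Tet1-/-_201_8 or the 3 ribosomal-rich oocytes of set Young_WT__246, were chosen after seeing the data. Counts of called genes below follow the order young Tet1KO against WT, young Tet2KO against WT, old Tet1KO against WT, old against young WT, old against young Tet1KO, the interaction, young Tet1KO against Tet2KO, and old Tet2KO against WT, where edgeR called 3, 2, 5, 6, 2, 0, 0 and 2. The counts were the same with no depth minimum, with at least 1000000 counts and with a minimum of 2-fold. The DESeq2 Wald test called 30, 16, 313, 331, 124, 17, 64 and 11, a test with more false calls on simulated data. Without a filter on low counts the calls were 252, 226, 564, 669, 377, 199, 536 and 243. With each oocyte a replicate, which treats oocytes of a set as independent, they were 2525, 3187, 1944, 4769, 1182, 1147, 3839 and 440. Where further counts moved, the cause was not tested. RLE normalization gave 9 in old Tet1KO and 1 in Tet1KO against Tet2KO. Without the naming series term, old against young WT and old against young Tet1KO had 0 and Tet1KO against Tet2KO 1 (437, 1128 and 1292 at an unadjusted p under 0.05). Limma on set means gave 0 in both young knockouts and in old Tet2KO and 10 in old against young WT (627, 1012, 271 and 1578 at an unadjusted p under 0.05). The T-series alone gave 9, 6 and 3 in the comparisons of young groups. The table of numbered libraries alone gave 13 in old Tet1KO against WT, all 5 genes of the full fit among them. It leaves young WT and young Tet1KO with 1 set each. There Tet1, Pnpla3 and Gm49513 lost their calls in young Tet1KO against WT, and Spint1, Mfap1b and Rps26 lost theirs in old against young WT. With the table as a term old Tet2KO had 1, and without S1616 it had 0 (edgeR, 227 at an unadjusted p under 0.05). Without Young_Tet1-/-_201_8 young Tet1KO against WT had 1 and against Tet2KO 1.

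Leaving out each set in turn, which can leave an arm with 1 set assumed to vary like the other groups, gave 3 to 8 genes in young Tet1KO against WT, 0 to 16 in old Tet1KO against WT (0 without Old_WT_247), 0 to 12 in old against young WT (0 without Old_WT_365 or Old_WT_247), and 1 to 181 in old against young Tet1KO (181 without Old_Tet1-/-_209). The interaction and young Tet1KO against Tet2KO had 0 to 3 and old Tet2KO 0 to 1 (0 without Old_WT_247). Of the results per gene followed in these leave-outs, the targeted genes apart, 500 kept their direction and side of the threshold, 35 lost and 2 gained a call, and 13 reversed. Of the called lists 63 results kept their call, 24 lost it and 5 reversed.

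Tet1 lost its call in young Tet1KO against WT with limma on set means (log2 change -2.70), in the T-series (-6.29) and in the numbered table (-9.78), and ranged from -9.70 to -6.26 over the sets left out. In old Tet1KO it gained a call with DESeq2 (-5.13), with no filter (-5.14) and with each oocyte a replicate (-4.54). These log2 changes are uncertain in size, since the knockouts hold 2 and 1 counts. With edgeR and limma they also depend on the prior count of each. With each oocyte a replicate Tet2 gained a call in young Tet2KO (-0.97), in old Tet2KO (-1.59) and in old against young WT (1.10), as did Tet1 in old against young WT (-1.26). In Tet1KO against Tet2KO Tet1 gained one with RLE (-7.26), DESeq2 (-7.49), no filter (-7.26), no naming series term (-7.26), each oocyte a replicate (-6.38) and without Young_Tet1-/-_201_8 (-7.19). Tet3, never called, changed sign near 0: in young Tet2KO it was 9e-04 with RLE, 9e-04 with DESeq2, 0.0095 with no filter, 0.018 in the T-series and -0.13 to 0.13 over the sets left out. In old Tet1KO it was 9e-04 with RLE, 6e-04 with DESeq2 and -0.26 to 0.18. Tet3 was -0.0191 in old against young Tet1KO and -0.0617 in the interaction with each oocyte a replicate. Over the sets left out it ranged from -0.0828 to 0.38, -0.16 to 0.28 and, in Tet1KO against Tet2KO, -0.23 to 0.0086. Over the sets left out Tet1 ranged from -1.46 to 2.07 in old against young WT, -2.75 to 3.28 in old against young Tet1KO (-0.11 with limma on set means) and -1.57 to 4.59 in the interaction, and Tet2 from -0.33 to 0.74 in old against young Tet1KO. Plk1 (-0.0606) and Xrcc2 (-0.24) reversed in old against young WT without the naming series term.

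At the preset correlation 17 list calls were made over all comparisons, and 1 held with an estimated correlation and 4 with fry. The respiratory chain list reversed in young Tet1KO against WT in the T-series (median 0.0442), without the ribosomal-rich oocytes (0.0635) and over the sets left out (-0.61 to 0.0552), and in old against young WT without those oocytes (0.25) and over the sets left out (-0.67 to 0.31). The ribosomal list reversed without those oocytes in old against young WT (0.0759) and in the interaction (-0.12, and -0.0123 to 1.01 over the sets left out). Without the naming series term its median shrank to -0.0164 in old against young Tet1KO, where the direction given by camera turned, and changed sign to 0.0531 in young Tet1KO against Tet2KO, where that direction did not turn. In PGCs 68 genes were 2-fold changed, 283 at a floor of 1 and 16 at a floor of 50, because the floor sets how many genes are counted. At a floor of 1 the apoptosis list turned from 0.0387 to -0.097. At that floor the imprinted list (-0.12) came to lie inside its random range, at percentile 6.66, and the medians of the meiotic prophase (-0.48), piRNA (-0.27), gonadal somatic (-0.56) and erythroid (-1.38) lists moved in size without turning. At a floor of 50 the imprinted (-0.50), methylation-silenced germline (-0.26) and erythroid (-1.82) lists did so. A pseudocount of 0.1 moved 15 of 71 PGC values, as it must for genes of low FPKM, such as Tet3 (-0.71), Taf7l (-2.35) and Gata4 (-1.52). As a mean over all oocytes, which gives large sets more weight, the share of protein-coding mitochondrial genes was 0.771% in old Tet1KO, 1.02% in old Tet2KO and 1.03% in old WT, and detected genes were 17206 in old Tet1KO and 17259 in old WT. Depth limits genes near 1 CPM, such as Tet1 and Tet2, and the simulations show that 2-fold changes of single genes were mostly out of reach of these numbers of sets.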

Other observations

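The tests of gene lists in this part were planned, none was added, and the genes named were chosen after their values were seen, from the lists on DNA methylation and maternal factors. Of the genes that write, keep or remove DNA methylation, young WT oocytes held 662 ± 29.2 CPM (SD, n = 4 sets) of Tet3, which oxidises the paternal genome after fertilization. The maintenance methylase Dnmt1 stood at 248 ± 44.9 CPM and its cofactor Uhrf1 at 332 ± 47.0. The de novo methylase Dnmt3a stood at 290.5 ± 87.2, its partner Dnmt3l at 71.6 ± 13.8 and Dnmt3b at 28.8 ± 4.46. Dppa3, which protects maternal methylation, stood at 1295 ± 133 CPM in young WT and 788 ± 237 in old WT (n = 2 sets), 1016 ± 688 in young Tet1KO (n = 2), 558 ± 410.0 in old Tet1KO (n = 2), 1211 ± 117 in young Tet2KO (n = 2) and 1390.1 in the old Tet2KO set. Tdg, the glycosylase that excises oxidised cytosine, was near 0 in every group, with at most 0.0452 CPM as a group mean.

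The 2 transcripts Gdf9 and Zbed3 were abundant in all groups, while some other oocyte transcripts were low, such as Zar1l, with group means of 7.09 to 18.9 CPM, and Khdc3, with 18.2 to 44.8. Gdf9, an oocyte-secreted growth factor, stood at 8303 ± 1814 CPM in young WT, 7131 ± 147 in old WT, 7555 ± 3766 in young Tet1KO, 6862 ± 1478 in young Tet2KO, 4981 ± 1457 in old Tet1KO and 8826 in the old Tet2KO set. Zbed3, of the subcortical maternal complex, stood at 20057 ± 1491 CPM in young WT, and the means of the other groups lay between 19273 and 27499. Lists of maternal-effect genes, oocyte identity genes and imprinted genes passed in no oocyte comparison with camera, with smallest adjusted p-values of 0.858, 0.488 and 0.577 over the comparisons.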
